A study of Homo sapiens with 6 samples.

How the data were processed

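Gene expression was measured in HEK293T, a human embryonic kidney cell line that carries the SV40 large T antigen, on 6 Illumina BeadChip arrays of 1 slide. Per the labels, 3 arrays held control cells and 3 held cells transfected with 4 µg of cloned hsa-miR-128, a microRNA best known from brain, and the series' design text calls them biological triplicates. The labels do not say whether the control cells received an empty plasmid or no transfection, nor which hairpin was cloned. Sections A to C of the slide carried the controls and sections D to F the transfected cells, so section and group are not balanced. The labels number no replicates; the numbers used here follow deposit order and pair no arrays. Per the labels' protocols, RNA was extracted with TRIzol, amplified into biotin-labelled cRNA with the Illumina TotalPrep kit and stained with streptavidin-Cy3.

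The deposited non-normalized table holds, per the file headers, 4 values per probe and array: the mean signal intensity over its beads, the number of beads, the standard error over beads and a detection p-value. The bead number and its standard error were used only to set differences between arrays against measurement noise. BeadStudio is the tool named in the submitters' processing notes, with no version given. The detection p-values deposited by the authors moved in steps of 0.00132, which implies 759 negative control probes. The second deposited table holds the authors' processed intensities. Set against the signal of the same array, each of its columns was a straight line of it (Pearson r at least 0.999997 over probes), with a background of 116 to 141 subtracted and the array mean brought to about 420. The medians of these columns were 9.47, 10.3 and 10.0 in controls 1 to 3 and 15.5, 12.5 and 10.5 in transfected arrays 1 to 3. They are on a linear scale, uncentred, and 26.5% to 28.1% of the values per array were below 0. The authors' name for this normalization is not given in the sources used here.

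Mean signal per array ran from 408 to 660 and the number of probes with a detection p under 0.01 from 12995 to 14345, with on average 36.3 to 38.1 beads per probe. The small number of arrays, 3 per group, limits the precision of every comparison. No pair of arrays repeated another: over probes detected on all 6 arrays, the typical difference between 2 arrays was 1.67 to 6.04 times that expected from the standard error over beads, the smallest being between controls 2 and 3.

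Signals were background corrected from the detection p, offset by 16, quantile normalized and put on the log2 scale as in neqc of limma 3.58.1 in R 4.3.3. One probe printed in a pair of rows was averaged, which left 48803 probes. Probe names came from the platform annotation given with the series, updated through the gene identifier to the symbols of RefSeq on GRCh38.p14: 27578 probes had 1 gene, 13 had several and 21212 were unnamed here. No coordinates are given, because the arrays name no genome build. Probes with a detection p under 0.01 on at least 3 arrays were kept (14200), of which 12101 had 1 gene. Each gene was represented by its kept probe with the highest mean, which gave 9797 genes; of 2052 genes with several kept probes, 495 had at least 1 probe whose fold change had the opposite sign. The groups were compared per gene with lmFit and eBayes, two-sided, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are transfected over control, on normalized log2 intensity. Errors of log2 fold changes are moderated standard errors. Where a gene was not detected on all arrays of its dimmer group, a bound is given as "at least", with the number of arrays that detected it: the mean of the brighter group against the mean, over the dimmer group's arrays, of the lowest signal among detected probes or the probe's own, whichever was higher.

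Of 25 gene lists fixed before the data were examined, 22 had at least 5 measured genes and were tested with camera (preset correlation of 0.01), adjusted over the lists, and again with a correlation estimated from these arrays and with fry. Camera asks whether a list moved relative to all other genes. The genes named in the text were fixed in advance as those with the largest changes past the threshold or, with none past it, the 5 with the smallest p in each direction; 10 reported miR-128 targets whatever their values; up to 4 members of each list past the threshold; and the 2 genes that host miR-128. Other named genes were chosen after their values were seen, which is said beside them. A planned test of miR-128 seed matches in 3′ UTRs was not run, because no UTR sequences were used here. On simulated data with the spread of these 9797 genes and 200 changed genes, the comparison of transfected with control arrays recovered 0% of genes changed by 0.5 on the log2 scale, 30% of those changed by 1, 88% of those changed by 2 and 96% of those changed by 3. The simulated genes varied independently, and the adjusted threshold depends on the share of changed genes. These rates hold for that setting and do not give the power of the real comparison.

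The alternatives tried were other background corrections and scalings, the authors' processed values, other detection filters, other ways to choose a probe, array weights, a trend with robust eBayes, an ordinary variance per gene, all probes separately, stricter thresholds, the slide section as a linear covariate and leaving out each array in turn. Correction for the genomic span of each gene was added after the data were seen, as were the NF-kB target list and the count of genes at an unadjusted p under 0.05.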

Results

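The series asked which transcripts differ in HEK293T cells after overexpression of miR-128, with 3 control arrays and 3 arrays of transfected cells. MicroRNAs act mainly by lowering the stability and translation of messenger RNAs that match their seed.

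Transfected arrays 1 and 2 lay farthest from the controls and transfected array 3 lay between them. On the first principal component, which held 52.1% of the variance, controls 1 to 3 stood at -13.66, -32.02 and -22.60, and transfected arrays 1 to 3 at 40.65, 28.56 and -0.92. The second component, with 31.7%, set control 1 (-30.87) and transfected array 1 (-22.38) apart from the other arrays, which stood between 1.04 and 23.92. Pearson correlations between arrays over genes were 0.950 to 0.993 within groups and 0.930 to 0.979 between groups, so the ranges overlapped. Transfected array 3 correlated at 0.959, 0.972 and 0.979 with controls 1 to 3, and at 0.950 and 0.979 with transfected arrays 1 and 2. Its typical difference, relative to the standard error over beads, was 4.48, 3.17 and 3.08 from controls 1 to 3. From transfected arrays 1 and 2 it was 4.63 and 3.56, so by this measure controls 2 and 3 were nearer. Transfected array 1 was the dimmest, with 12995 detected probes, and control 1 the brightest, with 14345. Fold changes also followed gene size: the Spearman correlation over genes of the log2 fold change with genomic span was 0.29, with longer genes higher in transfected cells.

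**Figure D1:**
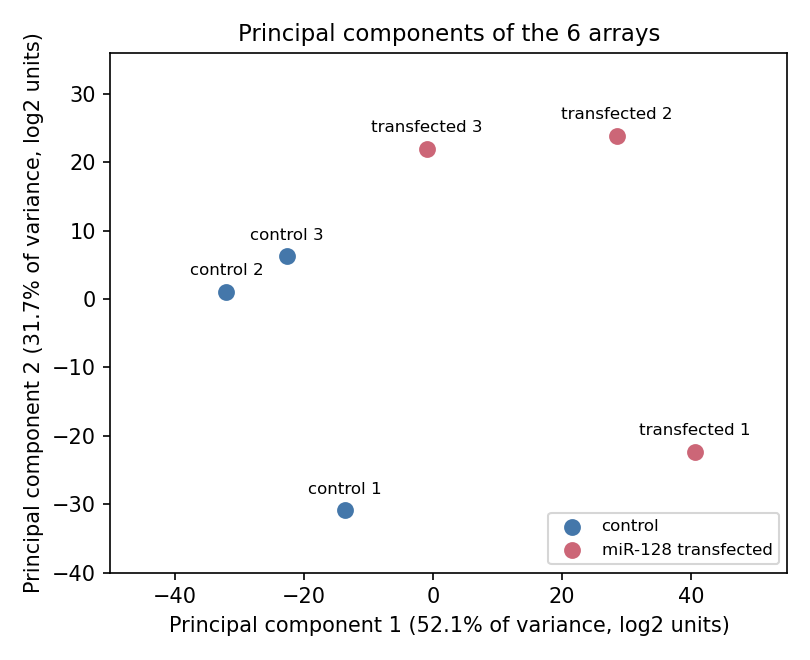
Each point is 1 array, placed by its first (x axis) and second (y axis) principal component of normalized log2 intensity over 9797 genes; colours mark the groups. Transfected array 3 stands at -0.92 on the first component, between the controls and the other transfected arrays.

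No single gene passed the limma test after Benjamini-Hochberg adjustment. Of 9797 genes, 0 had an adjusted p under 0.05, and 2799 had an unadjusted p under 0.05, where about 490 are expected by chance. Among these 2799, 1221 were higher and 1578 lower in transfected cells. The lowest adjusted p was 0.0501, shared by 171 genes, 61 higher and 110 lower. In 32.8% of genes the 3 transfected arrays lay wholly on one side of the 3 controls, where chance gives 10%. The count turned on the processing, with for example 273 genes past the threshold after cyclic loess, 452 without background correction and 5003 with array weights. It was 1628 without transfected array 3, 486 without transfected array 1, 14 without control 1, and 0 without control 2, control 3 or transfected array 2.

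The 5 higher genes with the smallest p all failed the adjustment, with an adjusted p of 0.0501 each. SYT14, a synaptotagmin, and CCDC81, a coiled-coil protein, were detected on all 3 transfected arrays and on none of the controls. Their signals were at least 1.37-fold and at least 1.90-fold higher, respectively. IFIT2, an interferon-induced antiviral protein, and IL7R, the interleukin-7 receptor, were each detected on 2 of the 3 controls and were at least 2.56-fold and at least 2.54-fold higher. TFPI2, a serine protease inhibitor of the extracellular matrix, was 3.11-fold higher (log2 difference 1.64 ± 0.25 SE, n = 3 per group). Of these, TFPI2 was already uneven among controls, with log2 intensities of 7.28, 6.49 and 6.66.

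The 5 lower genes with the smallest p also failed the adjustment at 0.0501. CEL, the bile salt-stimulated lipase, was at least 3.54-fold lower and was detected on 2 of the 3 transfected arrays. SOX18, a transcription factor of vessel development, was 3.15-fold lower (log2 difference -1.66 ± 0.22 SE). PTMS, which encodes parathymosin, was 2.52-fold lower (-1.34 ± 0.18), from a mean log2 intensity of 9.88 ± 0.20 (SD, n = 3) in controls to 8.54 ± 0.05 in transfected cells. SAMD1, a chromatin protein that binds unmethylated CpG islands, and TESMIN, a testis-expressed metallothionein-like protein, were detected on all controls and on none of the transfected arrays. Their signals were at least 1.39-fold and at least 2.05-fold lower.

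Genes reported elsewhere as direct miR-128 targets did not pass the test as a group. Of 35 such genes, 27 were measured, 19 of them higher and 8 lower in transfected cells, and the median log2 fold change was 0.26. Camera called no shift of the list (adjusted p = 0.155); with the slide section as covariate it was called as higher (adjusted p = 0.0131), and under the other 21 alternatives it was not (up to 0.795). No member passed over all genes tested, and 2 passed when adjusted over the list alone. At an unadjusted p under 0.05 stood 7 of the 27, against 2799 of all 9797 genes. With so many genes at that level, passes within a list need not be particular to the list, here and in the lists below. RXRA, the retinoid X receptor that partners the liver X receptors, was 1.97-fold lower (log2 difference -0.98 ± 0.16 SE), with log2 intensities of 9.20, 9.20 and 9.21 on the transfected arrays against 10.18 ± 0.12 (SD) in controls. SIRT1, a NAD-dependent deacetylase, was 2.01-fold higher (1.01 ± 0.19). Both had an adjusted p of 0.0501 over all genes. BAX, which permeabilizes mitochondria in apoptosis, was 1.54-fold lower (-0.62 ± 0.24, adjusted p = 0.143), and its groups overlapped, since control 1 (9.13) lay below transfected array 3 (9.18). The Polycomb proteins SUZ12 and BMI1 had log2 differences of 0.51 ± 0.18 and 0.39 ± 0.22, the cell cycle regulators E2F3 and WEE1 of 0.41 ± 0.19 and 0.46 ± 0.23. UPF1 and CASC3, which act in nonsense-mediated decay, had -0.46 ± 0.25 and -0.17 ± 0.27, and the cholesterol exporter ABCA1 had 0.10 ± 0.29. The adjusted p of these 7 genes was 0.116 to 0.848. With 1 array left out, UPF1 lay between -0.73 and -0.29, BMI1 between 0.25 and 0.61, WEE1 between 0.28 and 0.68, SUZ12 between 0.40 and 0.58 and E2F3 between 0.28 and 0.52. Without transfected array 3, UPF1, BMI1 and WEE1 passed the test (adjusted p = 0.0369, 0.0471 and 0.0423), as did RXRA and SIRT1 (0.0304 each). Of 20 alternatives, RXRA and SIRT1 passed under 9 each, UPF1, BMI1, WEE1 and BAX under 2 each, SUZ12 and E2F3 under 1, and CASC3 and ABCA1 under none. For SUZ12 and E2F3 the setting was array weights, under which 5003 of all 9797 genes passed. UPF1, BMI1 and WEE1 passed with array weights and without transfected array 3, where 1628 genes passed. BAX passed with array weights and with the slide section as covariate, where 1151 genes passed. With arrays scaled to equal medians 12 of the 27 targets were higher and 15 lower, with a median of -0.05, while the median of all genes moved from -0.03 to -0.33; 20 of the 27 were above that median gene under either scaling.

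**Figure D2:**
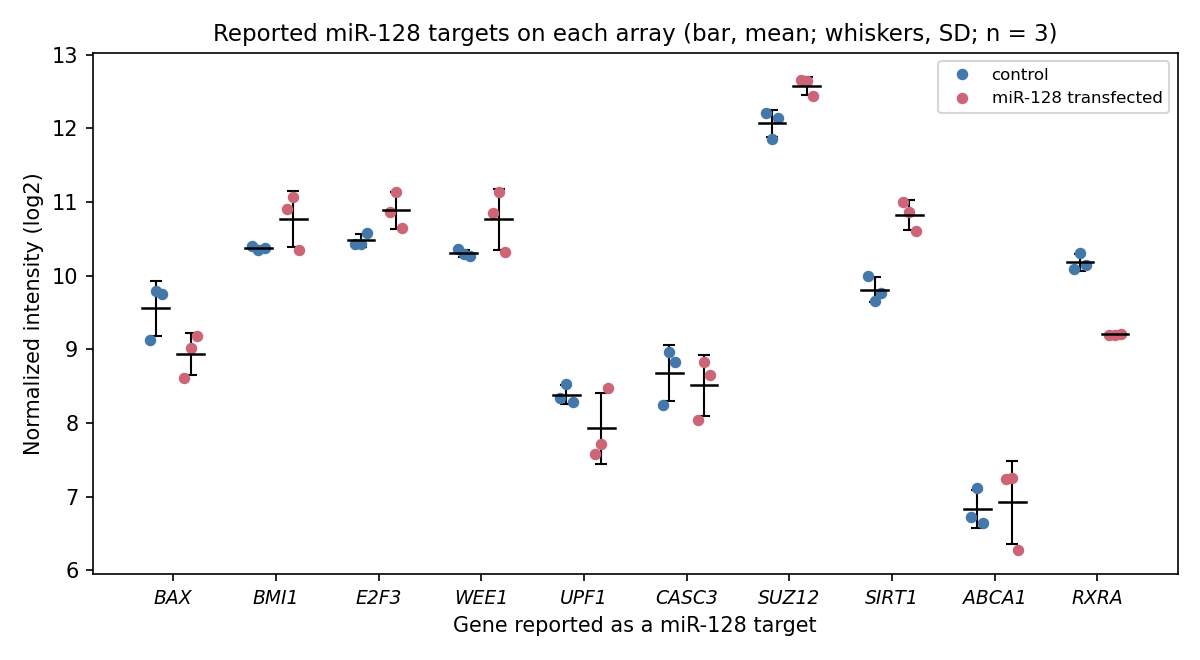
Normalized log2 intensity (y axis) of 10 genes reported as miR-128 targets on each of the 3 control and 3 transfected arrays (points), with the mean (bar) and SD (whiskers). RXRA is lower on all 3 transfected arrays and SIRT1 higher on all 3; neither passed the test over all genes.

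Of the genes that host the microRNA, R3HDM1, whose intron holds miR-128-1, was 1.72-fold higher in transfected cells (log2 difference 0.78 ± 0.22 SE, adjusted p = 0.0785), on both of its kept probes. ARPP21, the host of miR-128-2, had 7 probes on the array and was not detected often enough to be tested. The mature microRNA itself is not measured on this array.

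Genes of oxidative phosphorylation, the respiratory chain and ATP synthase, were lower in transfected cells. Of 65 measured members, 60 were lower and 5 higher, with a median log2 fold change of -0.34, and the list fell relative to other genes (camera adjusted p = 1.2e-05). With a correlation estimated from these arrays, the adjusted p = 0.626. No member passed over all genes and 2 passed when adjusted over the list alone. These 2, named after their values were seen, were the complex I subunits NDUFS7, 1.83-fold lower (log2 difference -0.87 ± 0.17 SE), and NDUFB4, at least 1.57-fold lower and detected on 1 of the 3 transfected arrays. Against controls 2 and 3, the list median was -0.35, -0.49 and -0.31 on transfected arrays 1 to 3, and -0.11 on control 1. Random lists matched on genomic span and intensity had a median of -0.10 (95% range -0.22 to 0.02).

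The cholesterol biosynthesis list had 15 of 16 measured members lower, a median log2 fold change of -0.49 and a camera adjusted p of 0.0273. The call was lost with an estimated correlation (adjusted p = 0.626). Fry, which asks only whether the genes of a list move one way, gave an adjusted p of 0.118. No member passed over all genes and 1 when adjusted over the list alone: LSS, lanosterol synthase, was 2.41-fold lower (-1.27 ± 0.24 SE). Relative to controls 2 and 3, the list median was -0.45 on control 1, against -0.73, -0.72 and -0.49 on the transfected arrays. SC5D, the one member above controls, had a log2 difference of 0.87 ± 0.27. The list of sterol efflux and liver X receptor genes had 10 of 12 members lower, with a median of -0.31 and an adjusted p of 0.0479. This call was lost with an estimated correlation (adjusted p = 0.626), with the slide section as covariate (0.311) and among genes detected on all arrays (0.0947). Relative to controls 2 and 3, its median was -0.15 on control 1, below the -0.12 of transfected array 1, and -0.37 and -0.50 on transfected arrays 2 and 3. None passed over all genes and 4 passed when adjusted over the list alone. Besides RXRA these were FASN, the fatty acid synthase, 2.40-fold lower (-1.26 ± 0.22), SREBF1, the transcription factor of lipid synthesis genes, at least 1.74-fold lower with detection on 1 of the 3 transfected arrays, and LPCAT3, a phospholipid acyltransferase, 1.55-fold lower (-0.63 ± 0.19). LSS, SC5D, FASN, SREBF1 and LPCAT3 were named after their values were seen. Without control 3 the adjusted p was 0.0923 for cholesterol biosynthesis and 0.0754 for the sterol efflux list; without transfected array 3 it was 0.0608 and 0.124, and the sterol efflux list also missed the threshold without control 2 (0.0501).

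Transcripts known as substrates of nonsense-mediated decay were higher relative to other genes. Of 19 measured, 15 were higher, the median log2 fold change was 0.36, and camera gave an adjusted p of 0.0273. This call was lost with an estimated correlation (adjusted p = 0.626) and with the slide section as covariate (0.0953). Fry gave an adjusted p of 0.0999. Relative to controls 2 and 3, the list median was 0.19 on control 1 and 0.39, 0.59 and 0.37 on the transfected arrays. When adjusted over the list alone 7 members passed, 6 higher and 1 lower, and over all genes none. Named after their values were seen, SMG1, a kinase of the decay pathway that is its own substrate, was 2.17-fold higher (1.12 ± 0.20 SE), RASSF1, a tumour suppressor, 1.91-fold higher (0.93 ± 0.24), and SRSF11, a splicing factor, 1.52-fold higher (0.60 ± 0.16). CDKN1A, the cyclin-dependent kinase inhibitor p21, was 1.71-fold lower (-0.78 ± 0.21). UPF2, also in this count, had 3 kept probes, 1 of them of opposite sign. With arrays scaled to equal medians 9 members were higher and 10 lower, and the list median was -0.0015 while that of all genes was -0.33. The list's adjusted p was 0.0923 without control 3 and 0.124 without transfected array 3. Decay factors as a group did not pass the test (12 measured, adjusted p = 0.597), and among them SMG1 alone passed when adjusted over the list alone.

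**Figure D3:**
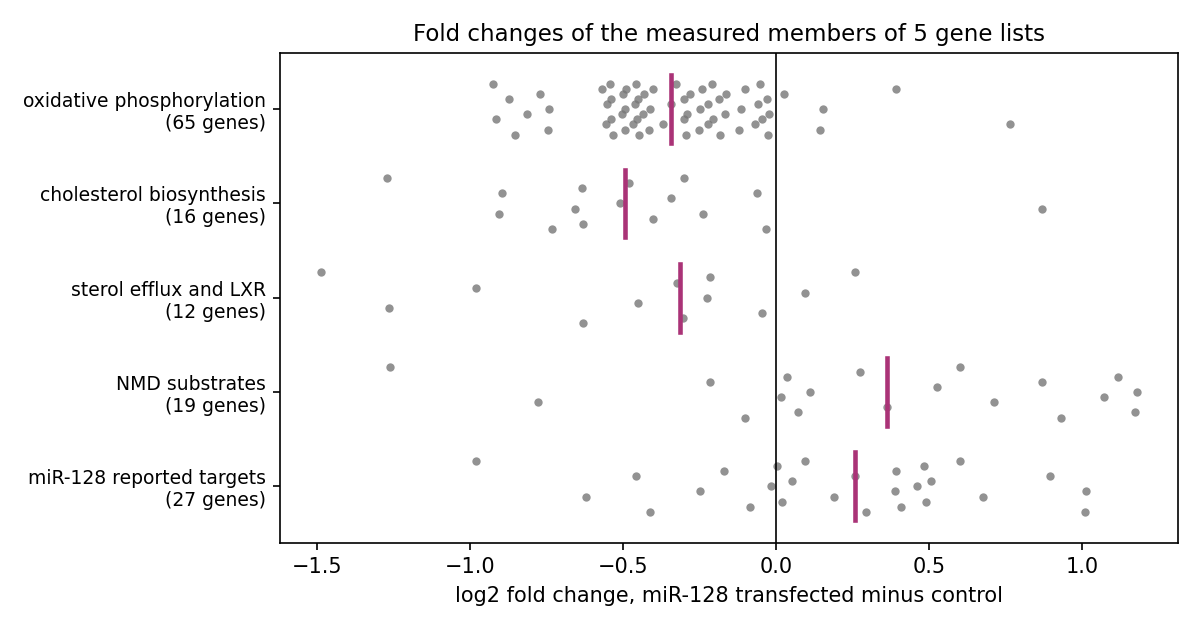
Log2 fold changes (x axis, transfected minus control) of the measured members of 5 gene lists (rows); each point is 1 gene and the vertical bar is the list's median. The medians are -0.34 for oxidative phosphorylation, -0.49 for cholesterol biosynthesis, -0.31 for sterol efflux, 0.36 for decay substrates and 0.26 for reported miR-128 targets.

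The lists of immediate early and integrated stress response genes did not pass the test. The immediate early list had 16 of 21 members higher and a median of 0.52 (0.45 with members at their bound; camera adjusted p = 0.0533), and the integrated stress response list 15 of 20 and 0.32 (adjusted p = 0.0776). With an estimated correlation the adjusted p = 0.930 for each. They were called as higher under 8 and 7 of 22 alternatives, with the lowest adjusted p without control 1 (1.53e-05 and 0.00017). The calls were not made under the other 14 and 15, for example by fry (0.510 for each) or without control 3 (0.242 and 0.314). Relative to controls 2 and 3, the immediate early median was 0.88 on control 1 and 1.15, 0.59 and 0.76 on transfected arrays 1 to 3. For the stress response list it was 0.76 on control 1 and 0.68, 0.44 and 0.47 on the transfected arrays. With arrays scaled to equal medians, 13 immediate early members were higher and 8 lower (median 0.17), and 10 and 10 of the stress response list (-0.02). The median of all genes was then -0.33, and 16 and 15 members of the 2 lists lay above it. Under that scaling camera called both lists as higher (adjusted p = 0.0002455 and 0.0231). No member of either list passed, over all genes or when adjusted over the list alone.

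The remaining lists did not pass the test. Interferon response genes split evenly, 8 higher and 8 lower (adjusted p = 0.592), with median and mean log2 fold changes of opposite sign (-0.03 and 0.16). When adjusted over the list alone 3 passed, IFIT2, the chemokine CXCL10, at least 2.66-fold higher and detected on 1 of the 3 controls, and IFI27, at least 1.48-fold lower and detected on 1 of the 3 transfected arrays, while none passed over all genes. Apoptosis regulators had 17 of 24 members lower (adjusted p = 0.597); adjusted over the list alone 2 passed, the anti-apoptotic BCL2L1, 1.77-fold lower (-0.82 ± 0.19), and the pro-apoptotic BMF, at least 1.59-fold lower and detected on none of the transfected arrays. Polycomb genes (adjusted p = 0.597) had 4 that passed when adjusted over the list alone, AEBP2, PCGF6 and EED with log2 differences of 0.92, 0.96 and 0.71 and CBX6 with -0.82. In the microRNA machinery (adjusted p = 0.328), DICER1, which cuts microRNA precursors, passed when adjusted over the list alone and was 1.89-fold higher (0.92 ± 0.18). Heat shock genes (adjusted p = 0.864) had 2, CHORDC1 (0.93 ± 0.24) and HSPA1A, at least 2.81-fold lower and detected on 2 of the 3 transfected arrays. Replication histones (adjusted p = 0.620) had 2, H4C8 (1.66 ± 0.33) and H2BC21, at least 1.76-fold higher and detected on 2 of the 3 controls. Hypoxia and glycolysis genes (adjusted p = 0.993) had PFKFB4 (-0.89 ± 0.21). All of these members were named after their values were seen, and none passed over all genes. At an unadjusted p under 0.05 stood 8 of 16 interferon response, 7 of 24 apoptosis, 8 of 21 Polycomb and 4 of 19 microRNA machinery genes. For heat shock it was 7 of 19, for replication histones 2 of 8 and for hypoxia and glycolysis 2 of 21. Of all 9797 genes, 2799 stood there, so passes within these lists need not be particular to them.

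The p53 targets (adjusted p = 0.169), chaperones of the endoplasmic reticulum (0.992), cell cycle genes of G1/S (0.597) and G2/M (0.993), cytosolic ribosomal proteins (0.992) and neuronal genes (0.993) had no member past the test, over all genes or adjusted over the list alone. Members of several lists went both ways, so that median and mean log2 fold change differed in sign, the test following the mean: 0.05 and -0.04 for G2/M, 0.03 and -0.02 for hypoxia and glycolysis, 0.02 and -0.04 for neuronal genes, -0.03 and 0.25 for replication histones, -0.003 and 0.03 for G1/S. With members at their bound the G1/S median was 0.005. With the slide section as covariate the G1/S list was called as lower (adjusted p = 0.00718), and after correction for gene span the ribosomal proteins were called as higher (0.0213).

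None of the measured blood, epithelial or hepatocyte markers was higher in the transfected cells. Of blood markers, HBA1 alone was measured (log2 difference -0.77 ± 0.18). Of fibroblast markers 6 of 7 were lower, with a median of -0.56, or -0.29 with members at their bound (adjusted p = 0.155). The 3 measured epithelial and hepatocyte markers were lower, KRT19 by a log2 difference of -0.88 ± 0.26 and SFN by -1.01 ± 0.27, and these 2 passed when adjusted over the list alone.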

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

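Among probes with no single gene name, which enter none of the gene comparisons, 9 were detected on all 3 transfected arrays and on none of the controls. They are listed because they give a signal outside the genes tested that was above the level of the controls. In the other direction, 30 such probes were detected on all controls and on none of the transfected arrays, and other splits of the 6 arrays into 3 and 3 gave up to 24 in a direction, so 9 is not a high number for these arrays. No biological explanation was tested.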

How the results depend on the processing

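The count of genes at an unadjusted p under 0.05, the correction for gene span and the NF-kB list were chosen after seeing the data; the other settings were planned. The planned seed match test and its alternatives were not run, since they need UTR sequences. No paired analysis was possible because the labels number no replicates.

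The count of 0 genes past the limma test became 452 without background correction (161 higher, 291 lower), 394 with an offset of 50, 273 after cyclic loess, 340 among genes detected on all arrays, 344 with a trend and robust eBayes, 1151 with the slide section as covariate, 5003 with array weights, and 1 with the authors' processed values or over all kept probes. Scaling to equal medians gave 373, 19 higher and 354 lower; at an unadjusted p under 0.05 it made 5.58% of genes higher, against 43.6%, as it moved the median of all genes to -0.33. Without detection filter, with a detection p under 0.05, with other choices of probe, without eBayes and after correction for span, 0 genes passed. Leaving out 1 array gave 0 to 1628. The 2799 genes at an unadjusted p under 0.05 became 5669 with array weights and 1488 (without control 2) to 3705 (without transfected array 3) with 1 array left out. The cause was not tested, except that fewer arrays were fitted when 1 was left out.

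Of the lists, 4 passed; 0 passed with an estimated correlation, 2 with fry, 7 after correction for span, and 1 (without control 3 or transfected array 3) to 6 (without control 1 or transfected array 2) with 1 array left out. Of the 22 alternatives, 1, the trend with robust eBayes, cannot change camera and repeated the main result for each list. Oxidative phosphorylation passed under 21 of 22, the exception being the estimated correlation, which took all 4 lists to an adjusted p of 0.626. The unadjusted camera p of oxidative phosphorylation was then 0.0595. Cholesterol biosynthesis passed under 18 of 22, with 0.118 by fry and 0.000677 to 0.0923 with 1 array left out. Decay substrates passed under 17, with 0.0999 by fry, 0.0953 with the section covariate and 0.00145 to 0.124 with 1 array left out. Sterol efflux passed under 16, with 0.0947 among genes detected on all arrays, 0.311 with the section covariate and 0.0234 to 0.124 with 1 array left out. The cause was not tested.

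Of the 21 named genes measured, 19 kept their direction under each alternative that gave a value. ABCA1 turned to -0.22 with equal medians and -0.050 after correction for span, and lay between -0.072 and 0.42 with 1 array left out, below 0 without transfected array 1 or 2; CASC3 lay between -0.39 and 0.067 with 1 array left out, above 0 without transfected array 1, and was lowest with the section covariate (-1.07). The named genes passed the adjusted test in 112 of 401 gene and setting pairs. Signal over background limits SYT14, CCDC81, SAMD1 and TESMIN, which 1 group did not detect.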

Other observations

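The tests of the first control, of admixed RNA in it, of the spread shared within groups as an explanation and of the splits for unadjusted counts and lists were chosen after the results were seen, as were the NF-kB target list and the bounds for genes that only some arrays of the dimmer group detected.

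Large fold differences were seen in several inflammatory genes, few of which were in the lists fixed in advance. The genes named here were chosen after their values were seen. A list of 42 genes induced by the transcription factor NF-kB was written after the fold changes had been seen, so its counts are no independent evidence. Of its 26 measured members 24 were higher in transfected cells, with a median log2 fold change of 1.23, or 1.03 with members at their bound (camera p = 1.18e-10; p = 0.0886 with an estimated correlation); none passed over all genes tested and 16 did when adjusted over the list alone. CXCL8, the neutrophil chemokine interleukin-8, was 10.4-fold higher (log2 difference 3.38 ± 0.83 SE, adjusted p = 0.0658). TNFAIP3, the feedback inhibitor A20, was 6.76-fold higher (2.76 ± 0.48, adjusted p = 0.0501). The chemokine CXCL2 and the cytokine TNF, each detected on 1 of the 3 controls, were at least 3.30-fold and at least 2.96-fold higher, and CCL20, detected on 2, at least 4.35-fold higher. SOD2, also a target of this factor, differed by -0.08 ± 0.18.

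Control 1 shared much of this difference. Its CXCL8 log2 intensity was 11.82, against 8.39 and 8.25 in the other controls and 13.27, 12.81 and 12.53 on the transfected arrays. TNFAIP3 stood at 8.16 there, against 6.28 and 6.15, and at 9.46 to 9.73 on the transfected arrays. Relative to controls 2 and 3 the median of the list was 1.11 on control 1 and 1.75, 1.65 and 1.54 on the transfected arrays. The NF-kB subunit gene NFKB1 did not follow: control 1 (10.26) was below the other controls (10.51 and 10.43), and the transfected arrays had 11.06, 12.13 and 11.98. Over genes, the deviations of control 1 and transfected array 1 from their group means correlated at 0.62, and those of the other 8 combinations of a control with a transfected array at -0.52 to 0.48; genes are not independent replicates.

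Brightness of the array was weighed for the inflammatory signal in control 1. That array had the highest mean signal, 659.9, but control 3, at 626.0, did not share the signal. Fitted without control 1, the slope of the list median on mean signal within groups gives an excess of -0.1048 (95% interval -0.139 to -0.0712, 5 arrays) for control 1, where 1.11 was seen. This argues against brightness as the cause, if its effect follows a straight line. Admixed transfected RNA would show in control 1 as a like percent of every rise, on a linear scale. For NF-kB targets the median percent was 45.7 (18 genes) and for other rising genes 39.3 (199 genes), a difference of 6.417 (95% bootstrap interval -9.88 to 35.8), so admixture cannot be told apart for these genes. Immediate early and stress response genes stood at 99.5% (12 genes), 60.24 above the other rising genes (36.9 to 110). This does not decide on admixture for them, since the test was chosen after they had been seen to be high on control 1. Their genes also move together (estimated correlations of 0.458 and 0.459), so the interval, which treats genes as independent, is too narrow. A shared culture state or handling of control 1 may lie behind their level there, a hypothesis on which the labels give no value to test, and so stays open. Whether miR-128 or the transfection itself raised the inflammatory genes was not tested, since the treatment of the controls is not stated.

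Lower oxidative phosphorylation genes were weighed against the trend of fold change with gene span. Only 0.02% of 10000 random lists matched on span and intensity had a median as low as -0.34, which argues against the trend as the whole cause. Spread shared by the genes of the list within groups stays open. With the correlation estimated from these arrays (0.079) the camera p was 0.0595 and the adjusted p 0.6263. This rise does not measure shared spread alone: the fibroblast list, with a negative estimated correlation (-0.077), also went from p = 0.0523 to 0.116. Fry, which asks only whether the genes move one way, gave an adjusted p of 0.0247 for oxidative phosphorylation. An effect of miR-128 or of transfection may also account for the lower genes and was not tested apart.

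Transfected array 3 lay nearer the controls than the other transfected arrays. Its slope on the mean difference of transfected arrays 1 and 2 was 0.449, and 0.4604 after correction for gene span. This was over 772 genes other than NF-kB targets that differed by at least 1 on the log2 scale on those 2 arrays. A linear correction for span thus changed the slope little. The slope does not decide on span, since genes picked for their difference on arrays 1 and 2 favour a slope under 1. Over genes, the difference of transfected array 3 from arrays 1 and 2 followed genomic span (Spearman correlation -0.27). Fewer transfected cells, or admixed control RNA, would leave a like percent of each rise. Immediate early and stress response genes kept a median of 47.7% (7 genes) and other rising genes 41.0% (251 genes), a difference of 6.632 (95% bootstrap interval -36.0 to 49.5), so this cannot be told apart with so few genes. NF-kB targets kept 75.1% (15 genes), but they were picked for being high on all transfected arrays, which favours a high percent.

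With 10 splits of the 6 arrays into 3 and 3, no share under 0.05 can be had. All 10 splits gave 0 genes past the adjusted test, and the highest other split also gave 0. At an unadjusted p under 0.05, 1 of the 10, the real one with 2799 genes, gave as many, and the highest other gave 1586; that split set control 1 with transfected arrays 1 and 2. For gene lists, 4 of the 10 splits gave at least the real 4, and the highest other, control 1 with transfected arrays 1 and 3 against the rest, gave 9, which points to a structure of the samples that the groups do not give. The mean trend over slide sections within groups correlated at -0.21 over genes with the group difference. This does not exclude a slide effect, since no section held both groups. Each trend also rests on 3 arrays and turns on control 1 in section A and transfected array 3 in section F.

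Outside the named genes, 1 unnamed probe passed when all 14200 kept probes were tested separately (adjusted p = 0.0246). It was detected on all controls and on no transfected array, with a signal at least 1.84-fold lower in transfected cells.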
